A study of Drosophila melanogaster with 6 samples.

How the data were processed

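RNA was measured in brains of 3rd instar Drosophila melanogaster larvae in which elav-Gal4, a driver active in neurons, expressed an RNAi construct against DMAP1. The labels hold 6 samples of this 1 genotype. Polyadenylated RNA was taken with a Qiagen column kit and made into Illumina TruSeq libraries, per the labels' protocols. The deposited values are whole-number counts of read pairs per gene, not normalized. Per the file headers they were made by featureCounts 1.6.5 with strand option 2, paired-end counting, a minimum overlap of 10 bases, an overlap of at least 0.1 of the read and at least 0.01 of the feature, no multi-mapping reads and no reads assigned to several genes, on an annotation of BDGP6 release 84. The folder named in the file headers points to HISAT2 alignments, whose version is not given in the sources used here. The submitters' processing notes also name DESeq2, with no role.

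The table holds 6 columns named for DMAP1 RNAi and 3 further columns of per-sample values named as wild type. The design text speaks of wild-type controls, but no sample in the labels used here matches these columns, which could belong to another series, so they were not analysed here. For that reason neither the size of the knockdown nor any effect of it is given. The 6 column names show the group but not which labelled sample each is. They fall into 2 series of 3, named DMAP1RNAi103734 and DMAP1RNAi63666, each numbered 1 to 3. The labels do not mention the series and do not say what the stems stand for. Comparisons between the series were added after the table was seen, from its column names. No label says that the samples came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

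Total counts per library ranged from 31518485 to 37236953, so 1 count equals 0.0269 to 0.0317 CPM, the count of a gene scaled to the total of its library. A count of 0 over 3 libraries is bounded here by 3 counts over those libraries. Intervals are exact Clopper-Pearson intervals at 95% and, like this bound, cover counting error only. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 24.61. Of the 17490 gene rows, 17216 were named by gene identifier in the Ensembl release 115 annotation, 214 by exon overlap of at least 0.8 with a gene on the same strand of the same assembly, and 60 kept their identifier. The strand option was checked on 45 antisense genes inside the span of a host gene, where the median ratio of antisense to host count density was 0.0035. Coordinates are those of the deposited table, on BDGP6.

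CPM and TPM, which also takes gene length into account, were computed from the deposited counts and the gene lengths in the same table. The named genes, the 34 gene lists and the tests within libraries were fixed before the data were examined. The named genes are DMAP1, the 17 members of a Tip60/Domino complex list, the marker genes w, v and y, the transmitter markers VAChT, VGlut and Gad1, the RNAs lncRNA:roX1 and lncRNA:roX2, His2Av, the 15 genes of highest mean TPM, the 2 members of highest mean TPM of every other list, and the 10 genes with the largest dispersion ratio past the threshold, of which there were none. Genes named outside this rule, which include most of those named between the series, were chosen after their values were seen. Of the genes of the lists, br and vas could not be matched to a single row.

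Within-library differences were tested by exact two-sided sign-flip permutation over the 6 libraries, whose smallest p is 0.03125. Benjamini-Hochberg adjustment was made over the 34 lists or the 3 marker pairs. The permutation treats the libraries as independent and takes no account of the series in the column names. Its p-values, and each SD with n = 6, therefore pool differences between the series with those within them. List abundance is the median log2(TPM + 1) of a list minus the median over genes kept by the filter of edgeR (minimum count 10). Genes varying among the libraries were tested with edgeR 4.0.16, with TMM factors from 0.916 to 1.037. Each gene's quasi-likelihood dispersion was set against the trend for its abundance in an intercept-only model of 9453 genes. List variability is the SD over libraries of the mean log2 CPM deviation of a list's kept members, as a percentile among 10000 random lists matched on expression. The series were compared with edgeR's quasi-likelihood test over 10211 genes, and adjusted p-values between the series come from that test unless another tool is named. Its filter asks for the minimum count in 3 libraries. It was set after a first run that asked for it in all 6, since that filter drops genes silent in 1 series. Sets were tested with camera and fry of limma 3.58.1. A correlation of DMAP1 with the lists was planned only if the libraries formed no separate clusters. On the first principal component of the 500 most variable genes the largest gap was 58% of the range, with 3 libraries on each side, so no correlation is given.

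On simulated counts the test for varying genes recovered 71% of genes given a log2 SD of 1, with 0 false calls in 3 runs on 9453 genes. The series test, on 10211 genes, recovered 45.8% of genes changed 1.5-fold, 77.6% at 2-fold and 96.5% at 4-fold, with 29 false calls over 3 runs. These simulated counts were drawn at the trended dispersion, without scatter of single genes around the trend. Recovery in the real counts may therefore be lower. For the varying-gene test the 71% does not carry over. Its prior degrees of freedom, which fall as single genes scatter more around the trend, were 3.62 in the real fit. Genes far above the trend did not pass there. In a test of list variability, 15 of 200 random lists and 20 of 20 lists given a common shift lay above percentile 95. Alternatives included DESeq2 1.42.0 size factors, Wald test and dispersion outliers, upper-quartile factors, no filter, other pseudocounts, CPM for TPM, means for medians and leaving out each library. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.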

Results

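Brain RNA was profiled in 6 libraries from 3rd instar larvae with neuronal RNAi against DMAP1, a subunit of the Tip60/Domino chromatin remodelling complex. The series title places DMAP1 in a neurodevelopmental disorder. The libraries held 34883561, 34322931 and 33700822 counts in the DMAP1RNAi103734 column-name series and 31518485, 34570126 and 37236953 in the DMAP1RNAi63666 series. Between 12855 and 13181 genes had at least 1 count. The labels give the 6 libraries 1 genotype, and without a mapped control the values describe the composition of these brains and the differences among the libraries.

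DMAP1 itself (FBgn0034537, chromosome 2R, 20644036 to 20645865, plus strand) was detected in all 6 libraries at 10.2 ± 2.76 CPM (SD, n = 6), or 15.03 ± 3.85 TPM. In the DMAP1RNAi103734 series it stood at 12.41 CPM (95% exact interval 11.27 to 13.64), 13.84 (12.62 to 15.14) and 11.72 (10.59 to 12.94). In the DMAP1RNAi63666 series it stood at 7.08 (6.18 to 8.07), 8.42 (7.48 to 9.44) and 8.00 (7.12 to 8.97). Relative to the median of 17 complex members in the same library, DMAP1 was lower by a log2 TPM difference of -2.17 ± 0.37 (SD, n = 6), on the same side in 6 of 6 libraries (exact sign-flip p = 0.03125, the smallest possible). The difference was -1.85 ± 0.12 (SD, n = 3) in the DMAP1RNAi103734 series and -2.49 ± 0.14 (SD, n = 3) in the other. Without a control sample this is a level, not a knockdown.

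The other members of the complex were spread over a wide range. Nipped-A, the large scaffold subunit, reached 189 ± 39.3 TPM (SD, n = 6), Bap55 170 ± 17.5 and dom, the Swi2/Snf2-type ATPase, 164 ± 13.3. The acetyltransferase Tip60 reached 25.3 ± 2.75 TPM. The ATPases pont and rept stood at 109 ± 10.6 and 91.5 ± 11.4, Hcf at 108 ± 16.4, Gas41 at 76.6 ± 11.96, E(Pc) at 76.4 ± 5.74 and Arp6 at 74.1 ± 11.3. Lower members were MRG15 (44.9 ± 7.17), YL-1 (43.2 ± 7.75), Eaf6 (31.7 ± 2.53), Brd8 (30.0 ± 5.14) and MrgBP (28.9 ± 10.7). By mean TPM, DMAP1 exceeded Act87E (12.5 ± 6.04) and Ing3 (4.18 ± 1.73), and 15 or 16 of the 17 members lay above it in each library. His2Av, the H2A variant that the complex exchanges, stood at 659 ± 72.0 TPM.

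**Figure D1:**
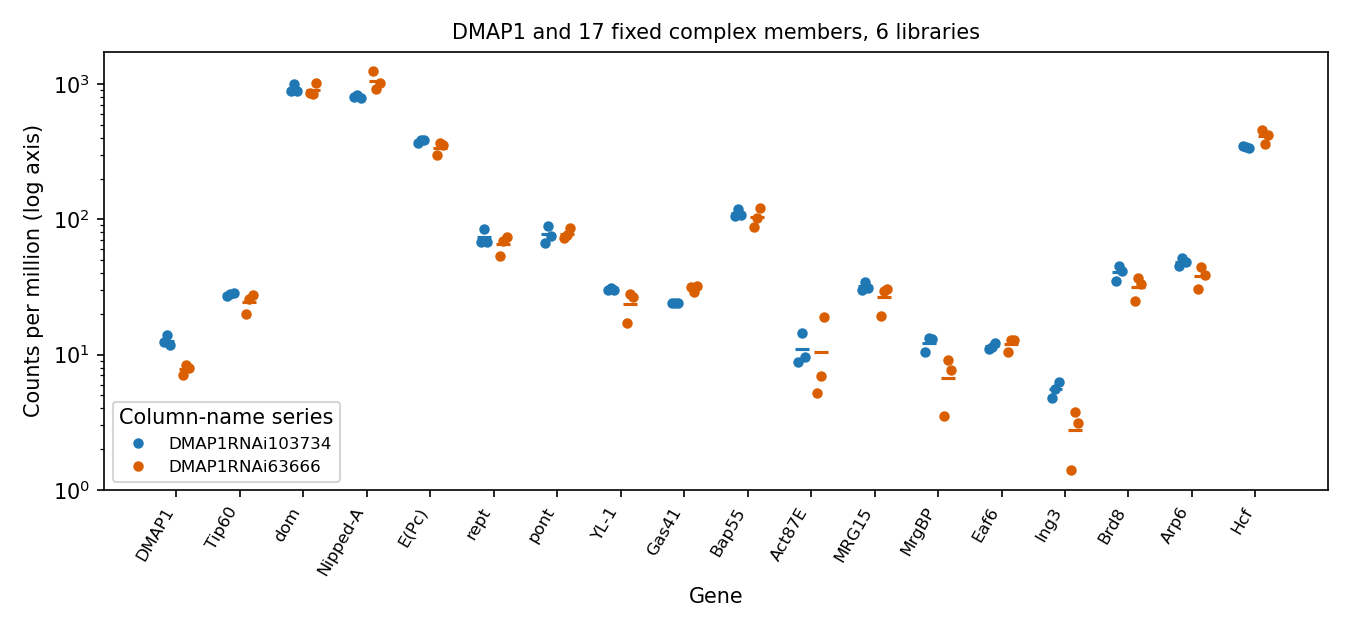
CPM (log axis) of DMAP1 and 17 complex members in each of the 6 libraries, as points colored by column-name series, with a line at each series mean. DMAP1 lies between 7.08 and 13.84 CPM, while dom lies at 916 ± 77.5 CPM (SD, n = 6).

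Most neuronal lists and the glial list lay above the median kept gene, while monoaminergic genes did not. The glial list had a median of 190 ± 11.4 TPM (SD, n = 6), against 33.5 ± 1.5 TPM for the median kept gene, led by Gs2 (2227 ± 96.1), a glutamine synthetase, and the GABA transporter Gat (837 ± 247). The pan-neuronal and synaptic list had 191 ± 46.9 TPM, led by nSyb (571 ± 96.7) and cpx (394 ± 93.6), both of the synaptic vesicle release machinery. GABA and glutamate markers stood at 256 ± 41.8, neuropeptides at 137 ± 14.2, cholinergic genes at 126 ± 21.7, axon guidance and adhesion genes at 103 ± 11.6 and cell cycle genes at 91.7 ± 7.95. Within the peptide list, Ilp2, an insulin-like peptide, reached 881 ± 114 and Proc 633 ± 80.2 TPM. Ribosomal protein genes had the highest list median, 1599 ± 449 TPM.

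Smaller positive offsets from the median kept gene, on the log2(TPM + 1) scale with SD over 6 libraries, were those of the Brahma complex (1.13 ± 0.22), the Tip60/Domino complex (0.96 ± 0.11), transmitter receptors (0.95 ± 0.27), DNA damage genes (0.73 ± 0.21), voltage-gated channels (0.62 ± 0.31), temporal factors (0.60 ± 0.42), apoptosis genes (0.45 ± 0.23), neuroblast genes (0.28 ± 0.18) and Polycomb group genes (0.22 ± 0.05). Below the median kept gene lay intermediate progenitor genes (-0.66 ± 0.13), optic lobe patterning genes (-0.69 ± 0.05), heat shock genes (-0.86 ± 0.16), muscle (-0.92 ± 0.54), ring gland (-1.05 ± 0.63), ecdysone response (-1.18 ± 0.19), wing and leg disc (-1.28 ± 0.10), hemocyte (-1.65 ± 0.64), cuticle (-2.45 ± 0.57), eye disc (-3.20 ± 0.18), germline (-4.57 ± 0.11), antimicrobial peptide and immune (-4.82 ± 0.26), gut (-4.89 ± 0.17) and salivary gland genes (-5.09 ± 0.08). The mitochondrial genome list lay at -2.997 ± 0.527 because its 37 members include tRNA genes, although the list took 8.15 ± 1.56% of all counts. Each of these 32 lists, 17 above and 15 below, was on its side of the median in 6 of 6 libraries (exact sign-flip p = 0.03125, adjusted p = 0.0332). That p is the smallest possible and says only that the side was the same in every library. Lists with most members removed by the filter were bound to lie below the kept genes. Such lists were salivary gland (0 of 8 kept), gut (1 of 7), antimicrobial (2 of 21) and germline genes (7 of 15). Monoaminergic genes (-0.17 ± 0.24, 5 of 6 libraries, exact adjusted p = 0.156) and fat body genes (-1.74 ± 1.27, 5 of 6 libraries, exact adjusted p = 0.0644) did not pass. The monoaminergic list turned to the other side with the mean of the list (0.24) and with no filter on low counts (1.51), each with an exact adjusted p of 0.0354, and with CPM (0.34, exact adjusted p = 0.0686). Directions are relative to the genes kept by the filter. With no filter on low counts, 8 of the lists below the median lay above it (24 lists above and 6 below passed, against 17 and 15), and cuticle, hemocyte and muscle genes no longer passed. Scaling by CPM turned the sign of apoptosis and ecdysone response genes and ended the call of intermediate progenitor, hemocyte and muscle genes, while the mean of a list in place of its median turned temporal factors and ended the call of apoptosis and mitochondrial genome genes.

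**Figure D2:**
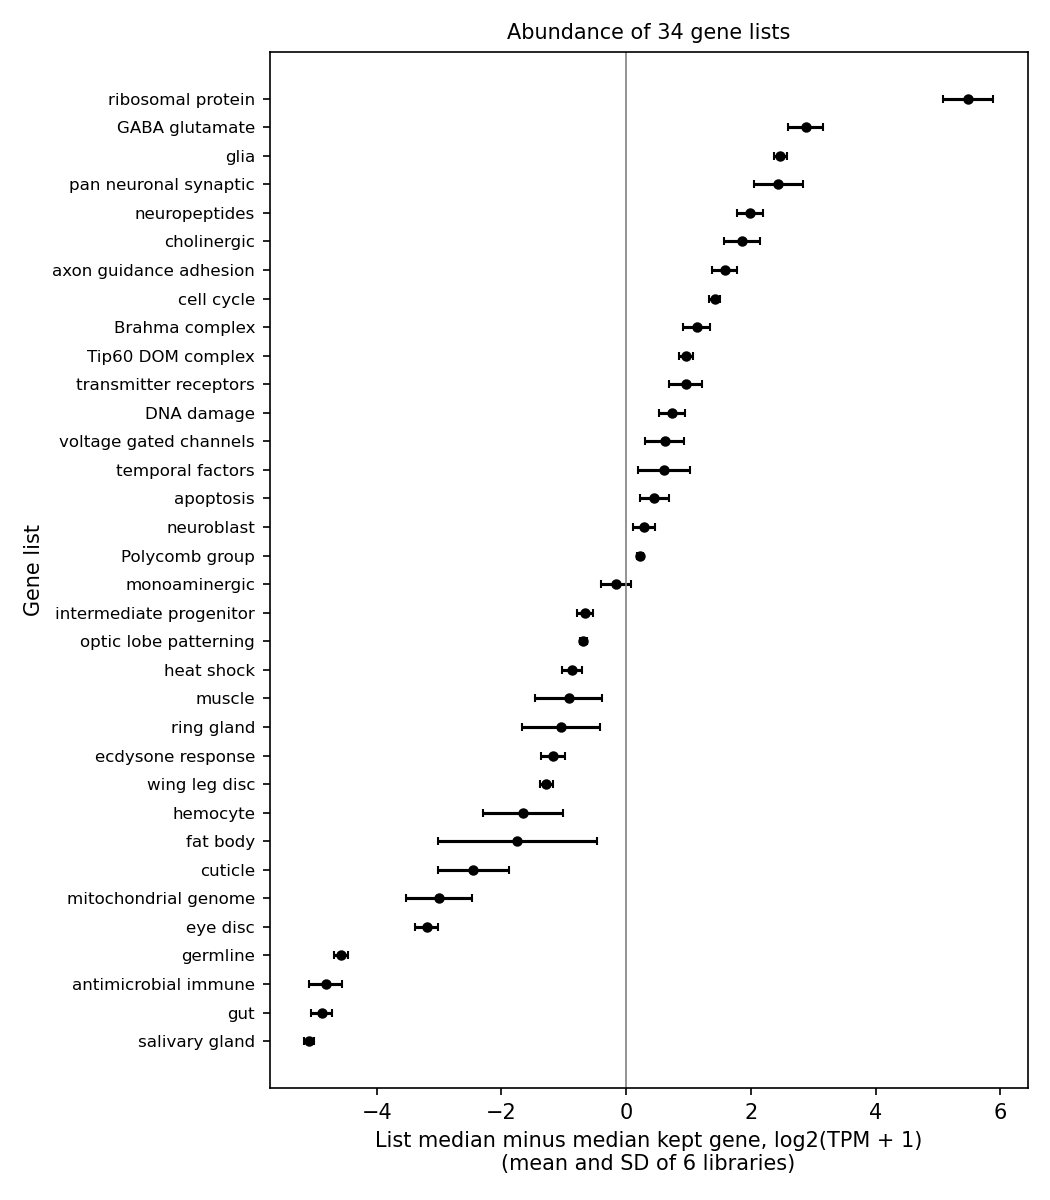
Median of each of 34 gene lists minus the median kept gene, log2(TPM + 1), with points at the mean and bars for the SD of 6 libraries. Ribosomal protein genes lie at 5.48 ± 0.40 and salivary gland genes at -5.09 ± 0.08.

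Among single genes, the mitochondrial ribosomal RNA mt:lrRNA had the highest mean, 94781 ± 17110 TPM (SD, n = 6), followed by mt:CoIII, RpL41, mt:CoI and eEF1alpha1. The long noncoding RNA lncRNA:cherub ranked 9 by mean TPM and took 23394 ± 6539 CPM. The odorant-binding protein gene Obp44a ranked 15 at 4715 ± 1640 TPM. lncRNA:roX1 and lncRNA:roX2, RNAs of the male dosage compensation complex, were present at 1434 ± 187 and 44.1 ± 9.44 CPM.

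The order of transmitter markers was the same in every library for the 3 genes fixed in advance. Gad1, the GABA synthesis enzyme, stood at 524 ± 53.8 TPM (SD, n = 6), the vesicular glutamate transporter VGlut at 256 ± 41.8 and the vesicular acetylcholine transporter VAChT at 121 ± 21.5. VAChT minus VGlut was -1.08 ± 0.03 on the log2 scale, VAChT minus Gad1 was -2.12 ± 0.24, and Gad1 minus VGlut was 1.05 ± 0.22, each on 1 side in 6 of 6 libraries (exact sign-flip p = 0.03125, adjusted p = 0.03125). Without gene length, on CPM, Gad1 minus VGlut was 0.30 and VAChT minus Gad1 -1.18. With ChAT and VGAT as the markers, ChAT minus VGlut was -2.38 and ChAT minus VGAT -0.94, so the place of GABA depended on the marker. With VGAT, the vesicular GABA transporter (93.9 ± 10.3 TPM), in place of Gad1, the GABA marker lay below VGlut by a log2 difference of -1.44 ± 0.09 in the 6 libraries.

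Cyp4p2, y and w had dispersions of 447, 265 and 150 times the trend for their abundance over the 6 libraries, without passing the edgeR test for varying genes (adjusted p = 0.33, 0.42 and 0.59). In that test 0 of 9453 genes passed an adjusted p of 0.05 and 385 had an unadjusted p under 0.05. Since genes this far above the trend did not pass, the test had little power in these counts. The 0 therefore does not show that genes did not vary. DESeq2 called 49 dispersion outliers, and without the filter edgeR called 4 genes. Beyond counting noise, 8524 genes (90.2%) varied. The biological coefficient of variation was 18.2% over 6 libraries on the 9453 genes. Within the column-name series it was 15.2%, on the 10211 genes of the series test, so these values also differ in gene set.

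Groups of genes moved together among the libraries. Of 31 lists with at least 3 kept members, 17 had a larger SD of the list mean than 95% of matched random lists, where chance gives 1.6. The widest was the fat body list, with an SD of 1.17 log2 units over its 6 kept members and deviations from -1.17 to 2.05. Cuticle genes had an SD of 0.72, mitochondrial genome genes 0.59, muscle 0.48, ring gland 0.43, hemocyte 0.37, ribosomal protein genes 0.35, and temporal factors and heat shock genes 0.30 each. Part of this spread lay between the column-name series, within which the SD was 0.30 for mitochondrial genome genes and 0.13 for heat shock genes. Without library 2 of the DMAP1RNAi103734 series the SD was 0.68 for fat body and 0.31 for cuticle genes, which still passed (percentiles 99.7 and 96.1). Neuronal lists varied less in size but also together. Voltage-gated channels had an SD of 0.27, synaptic genes 0.25 and transmitter receptors 0.24, each with its highest mean in library 1 of the DMAP1RNAi63666 series (0.40, 0.43 and 0.37) and its lowest in library 2 of the DMAP1RNAi103734 series (-0.36, -0.33 and -0.36). The Brahma complex (0.19), Tip60/Domino complex (0.14), ecdysone response (0.14), cell cycle (0.09) and neuropeptide lists (0.09) also passed. Without library 1 of the DMAP1RNAi63666 series, the Tip60/Domino list fell to percentile 86.9 and the ecdysone list to 39.0, and the SD of Brahma complex and synaptic genes to 0.10 and 0.14 (percentiles 96.3 and 97.8). Temporal factors fell to 71.1 without library 3 of the DMAP1RNAi103734 series, and neuropeptides to 84.1 and cell cycle genes to 94.3 without library 2 of that series. The ecdysone list also lay below 95 without library 1 of the DMAP1RNAi103734 series (93.8) or library 2 of the DMAP1RNAi63666 series (93.4), and neuropeptides without the latter (94.3) or within the column-name series (92.6). The remaining 14 lists lay below percentile 95, namely cholinergic (94.8), glia (93.1), eye disc (92.4), apoptosis (91.7), monoaminergic (90.5), wing and leg disc (87.1), intermediate progenitor (85.2), GABA and glutamate (83.1), DNA damage (82.8), axon guidance (71.6), neuroblast (69.7), Polycomb group (66.3), optic lobe patterning (53) and germline genes (39.1). Of these, the cholinergic, monoaminergic, intermediate progenitor and apoptosis lists passed without 1 library in at least 1 case (97.0, 97.6, 97.1 and 95.7 at the highest). Within the column-name series, cholinergic (97.6), monoaminergic (98.1), intermediate progenitor (95.1), eye disc (96.2) and wing and leg disc genes (95.9) passed, and DNA damage genes lay at 6.0. The antimicrobial, salivary gland and gut lists had under 3 kept members and were not tested.

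**Figure D3:**
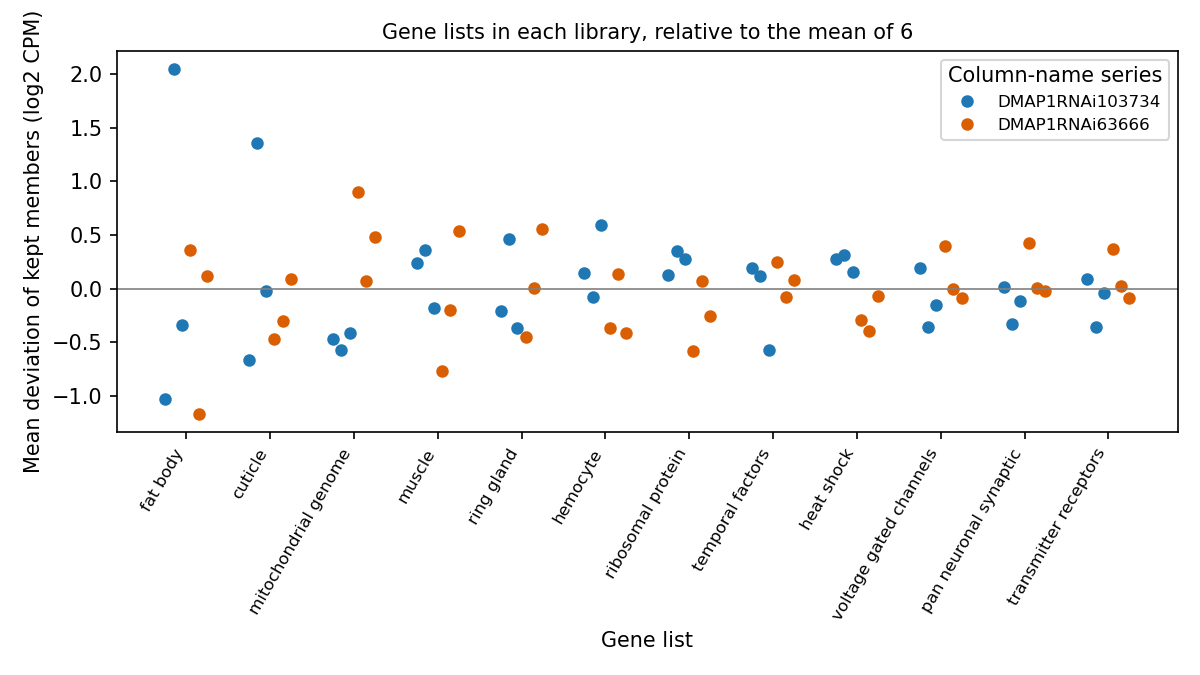
Mean log2 CPM deviation of the kept members of 12 gene lists in each of the 6 libraries, colored by column-name series. The fat body list spans -1.17 to 2.05 and the transmitter receptor list -0.36 to 0.37.

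The column names divide the libraries into 2 series of 3, and between these 158 genes differed, 89 higher and 69 lower in the DMAP1RNAi63666 series. The labels do not state what the series are. The eye pigment transporter gene w (chromosome X) stood at 1718 ± 150 CPM (SD, n = 3) in the DMAP1RNAi103734 series and 54.9 ± 8.90 in the other, a log2 fold change of -4.90 (SE 0.14, adjusted p = 1.4e-06). The body color gene y stood at 5.26 ± 0.36 and 174 ± 31.997 CPM, a log2 fold change of 5.13 (SE 0.19, adjusted p = 6.8e-06). The eye pigment gene v stood at 0.51 ± 0.09 and 5.77 ± 0.83 CPM, a log2 fold change of 3.58 (SE 0.25, adjusted p = 0.00028). These 3 calls held under every alternative run.

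Some cytochrome P450 genes, chosen after their values were seen and not tested as a group, differed between the series. The neighbors Cyp4p1, Cyp4p2 and Cyp4p3 on chromosome 2R were higher in the DMAP1RNAi63666 series by log2 fold changes of 7.29 (SE 0.20), 8.25 (SE 0.21) and 4.45 (SE 0.35). Cyp6a17 had 3 counts in the DMAP1RNAi103734 series and 4777 in the other, a ratio of 1586 (95% exact interval 542 to 7693). Cyp6a20 and Cyp28a5 were higher by 1.31 (SE 0.18) and 1.04 (SE 0.11), whereas Cyp6w1 changed by -2.74 (SE 0.33). The adjusted p of these genes was at most 0.0094 in edgeR, and their calls held under every alternative in which they were tested. Some genes were silent in 1 series. CG34109 was at 0 in the DMAP1RNAi63666 series and at least 149.61-fold lower there, and asRNA:CR45822 and CG18765 were at 0 in the DMAP1RNAi103734 series and at least 218.78-fold and 129.81-fold higher in the other, with the bound at 3 counts over the 3 libraries. At most 3 counts were seen in the DMAP1RNAi103734 series for 6 called genes and in the DMAP1RNAi63666 series for 8.

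**Figure D4:**
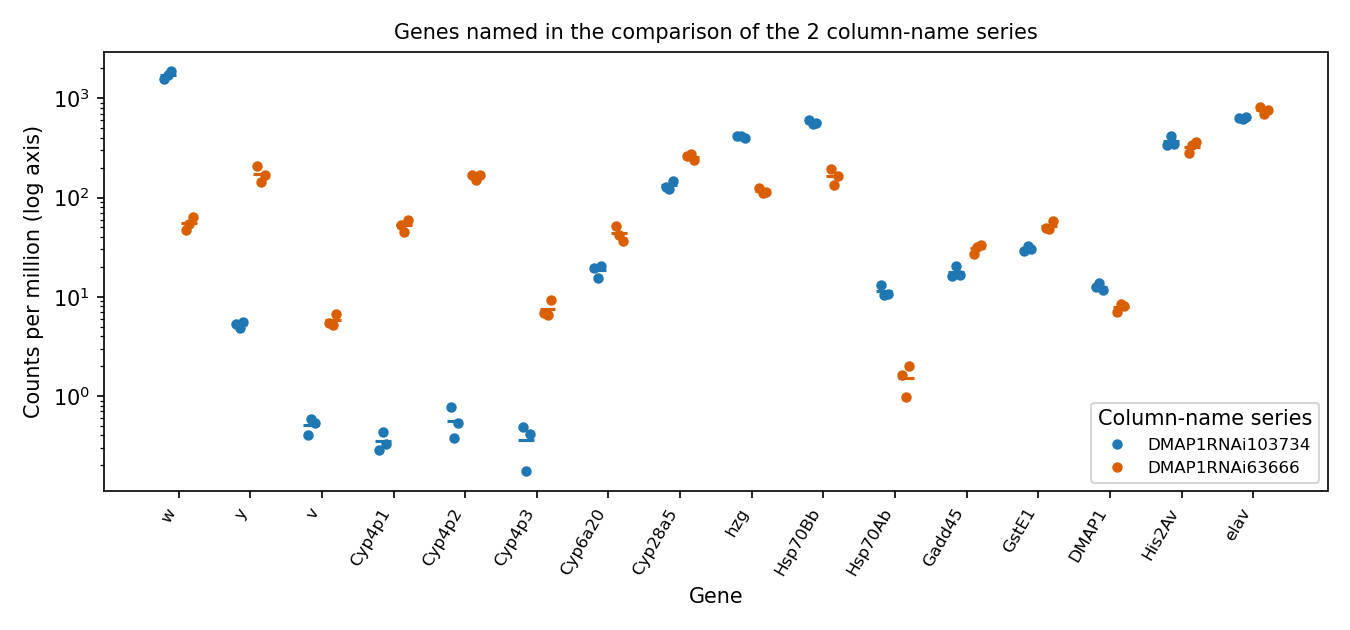
CPM (log axis) of 16 genes in each of the 6 libraries, colored by column-name series, with a line at each series mean. w lies at 1718 ± 150 and 54.9 ± 8.90 CPM (SD, n = 3), and Cyp4p2 at 0.56 ± 0.20 and 164 ± 11.2 CPM.

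Among the fixed lists, 4 of 14 tested heat shock genes were lower in the DMAP1RNAi63666 series, and 5 adjusted over the list alone. Hsp70Bb changed by -1.72 (SE 0.17, adjusted p = 0.0019), and Hsp70Ab, Hsp70Aa and Hsp70Ba by -2.81, -3.32 and -1.40. The call of Hsp70Ba was lost without any library (adjusted p = 0.0524 to 0.168) except library 1 of the DMAP1RNAi63666 series. These are near-identical copies whose reads cannot be assigned with certainty. The list's adjusted p in camera was 3.6e-05 with a preset correlation and 0.82 with an estimated correlation. In fry its adjusted p was 0.071 for a move in 1 direction and 0.0015 for members moving either way. Of 17 tested mitochondrial genome genes, 6 were higher (mt:ATPase6, mt:ND1, mt:ND2, mt:ND3, mt:ND4 and mt:ND5), and 16 adjusted over the list alone. mt:ND5 changed by 1.17 (SE 0.19, adjusted p = 0.025) and mt:ATPase6 by 0.95 (SE 0.15, adjusted p = 0.022). All 6 calls were lost without any 1 library of the DMAP1RNAi103734 series (adjusted p = 0.06 to 0.139), all but that of mt:ND3 without library 3 of the other (0.0548 to 0.0791), and that of mt:ND2 without its library 1 (0.0545). The mitochondrial list had an adjusted p of 1.8e-15 in camera with a preset correlation and an adjusted p of 0.98 with an estimated correlation. Mitochondrial genes took 6.98, 6.88 and 7.10% of counts in the DMAP1RNAi103734 series and 10.91, 8.85 and 8.18% in the other.

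No ribosomal protein gene of 86 tested was called over all genes by edgeR, while 55 were lower and 2 higher adjusted over the list alone, with a median log2 fold change of -0.52. The list's adjusted p was 1.9e-13 with a preset correlation and 0.98 with an estimated correlation. Synaptic genes had 0 of 15 called by either count, a median of 0.28, and adjusted p = 0.013 and 0.98 in the same tests. That median was 0.11 without library 1 of the DMAP1RNAi63666 series and 0.17 without library 2 of the other. No list passed with an estimated correlation. In fry, which asks whether a list moves 1 way without comparing it with other genes, the DNA damage list passed (adjusted p = 0.0117), with 3 of 8 members higher adjusted over the list alone and 0 over all genes. Its member Irbp18 had a log2 fold change of 0.61 (SE 0.15, adjusted p = 0.09) and Xrp1 of -0.02 (SE 0.09, adjusted p = 0.92), neither past the threshold over all genes. Adjusted over the list alone, 3 of 31 neuropeptide, 2 of 12 apoptosis, 1 of 8 germline and 1 of 17 Tip60/Domino genes were higher, and over all genes 0 of each. The other lists tested had no called member by either count.

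DMAP1 was lower in the DMAP1RNAi63666 series by a log2 fold change of -0.62 (SE 0.12), close to the threshold at an adjusted p of 0.045 in edgeR. The value stayed between -0.56 and -0.68 under all alternatives, but the call was lost when the filter asked for the minimum count in all 6 libraries (adjusted p = 0.0647), with a replicate block (0.0507) and without any single library except library 2 of the DMAP1RNAi63666 series (0.0774 to 0.168). Other members of the complex were not called. Called genes outside the lists, chosen after their values were seen, included hzg (-1.74, SE 0.10, adjusted p = 0.00012), eIF3b (-0.69, SE 0.12, adjusted p = 0.032), GstE1 (0.83, SE 0.09, adjusted p = 0.0039) and the stress-response gene Gadd45 (0.87, SE 0.11, adjusted p = 0.0078). The call of eIF3b was lost without any library of the DMAP1RNAi103734 series (adjusted p = 0.112 to 0.183) or library 3 of the other (0.0817), and that of Gadd45 without library 1 or 3 of the DMAP1RNAi103734 series (0.0565 and 0.055). The number of calls depended on the method. DESeq2's Wald test called 959 genes, and the first filter, which asked for the minimum count in all 6 libraries, gave 90. Without library 1, 2 or 3 of the DMAP1RNAi103734 series 75, 83 or 69 genes were called, and without library 2 of the DMAP1RNAi63666 series 457.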

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

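Each fixed named gene, list mean and depth measure was searched for a library far from the other 5. Of 136 measures, 17 had such a library, against 6.8 at a rate of 1 in 20, which holds for independent, normally distributed values. Of these measures 101 were CPM values of genes, not on a log scale, and related genes and lists were counted separately. The 17 are therefore no test of an excess. The comparison of the series, the test on neighboring genes, the reading of DMAP1 as a cause and the test of a shared tissue amount were chosen only after the results were seen.

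Library 1 of the DMAP1RNAi63666 series stood apart most often. It had the fewest genes detected (12855, against 13095 to 13181) and also the fewest counts (31518485). The CPM values of this search carry no TMM factor. This library had the lowest factor (0.916) and the highest mitochondrial share of counts (10.91%), so part of its low values may lie in its composition. The library was lowest for Tip60 at 20.1 CPM (others 25.7 to 28.7), E(Pc) at 296 (357 to 387), YL-1 at 16.97 (26.4 to 30.9), MRG15 at 19.3 (29.7 to 34.4) and the photoreceptor gene sev at 67.5 (112 to 136). It was highest for RpS3A at 3645 CPM (2651 to 2977) and for the ecdysone response list, at a mean deviation of 0.26 (-0.10 to 0.02).

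Library 2 of the DMAP1RNAi103734 series was highest for the larval serum protein gene Lsp1beta at 229 CPM (others 25.5 to 57.7), the cuticle gene Lcp4 at 44.7 (1.56 to 8.08), the salivary gland gene ng2 at 1.86 (0.0 to 0.59), ato at 4.95 (1.05 to 2.34) and the cuticle list at a mean deviation of 1.36 (-0.66 to 0.09). It was lowest for the monoaminergic list, at -0.23 (-0.03 to 0.07). Library 2 of the DMAP1RNAi63666 series was highest for RpL21 at 2039 CPM (1761 to 1864) and for ng1 at 0.46 CPM (0.0 to 0.12). Library 3 of that series was highest for the chaperone gene Hsp83, at 2003 CPM (778 to 1109).

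Fat body, hemocyte and muscle genes varied among the libraries. One shared amount of other tissue, as from rougher dissection, would raise the 3 lists together, but their means lay on the same side of their average in 0 of 6 libraries. That goes against it as the main source of these 3 means, but does not exclude a smaller shared amount. Other tissue lists were outside this test. In library 2 of the DMAP1RNAi103734 series, cuticle (1.36), eye disc (0.52), ring gland (0.46) and wing and leg disc genes (0.25) lay above their average. There fat body (2.05) and muscle (0.36) did so too, but hemocyte genes did not (-0.08). Several tissues shared in that library therefore stay open. The fat body mean need not measure tissue. Between the series apolpp and Apoltp changed by 0.38 and 0.35 and the other tested members by -0.70 to -3.33, none of them called. Separate amounts of each tissue may contribute, but the evidence is one of signs. Other genes of these tissues, in no list, lay on the side of their tissue's list in 16 of 18 pairs of library and tissue, that is 6 of 6 for hemocyte (Sr-CI, crq, Glt), 6 of 6 for muscle (such as Zasp66 and Mlp84B) and 4 of 6 for fat body (Tsf1, FASN1, Lpin), but some of these lay near 0 (-0.03 for hemocyte in library 1 of the DMAP1RNAi63666 series) and most muscle and fat body ones moved far less than the list (0.38 against 2.05 for fat body in library 2 of the DMAP1RNAi103734 series, and -0.18 against -0.77 for muscle in library 1 of the other). The most abundant members of the lists averaged 1092 CPM for apolpp, 254 for Col4a1 and 124 for Act57B, and how many of these genes brain cells also express was not measured, so a change of expression within the brain stays open, as does larval age.

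The 158 genes that differed between the column-name series are the second pattern. The 10 ways to split 6 libraries into 3 and 3 are too few for a share under 0.05, with 158 genes called by the real split, the 1 split to call as many, and 0 by the highest other. A linked genetic background may account for part of it, since called genes lay next to each other 8.4 times as often as in 10000 shuffles (19 pairs against 2.26, one-sided permutation p = 0.0001, the smallest possible). The same number of top genes from the other splits gave ratios of 1.3 to 5.8, so neighbors that vary together for other reasons cannot be told apart from it. The genes w, v and y, which many fly transgenes carry, were all called, w lower and v and y higher in the DMAP1RNAi63666 series. They may reflect the transgenes themselves rather than linkage, and the labels do not say whether the series carry different ones. A different DMAP1 level also cannot be told apart, because DMAP1 itself differed between the series (log2 fold change -0.62).

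The third pattern is the lower median of ribosomal protein genes in the DMAP1RNAi63666 series, a log2 fold change of -0.52 with an SE between libraries of 0.20, which did not pass as a group (adjusted p = 0.98 with an estimated correlation, and 0 of 86 genes called over all genes by edgeR, against 55 lower and 2 higher adjusted over the list alone). The tables argue against a gene length trend, since the median was -0.52 after a fit on gene length was taken off, a fit that moved other genes by up to 0.40. One library may carry part of it. Without library 1 of that series the median was -0.38 (SE 0.15), below the bound of -0.25 set in advance for a shift not carried by that library. It lies within 1 SE of that bound, a margin not set in advance, so the share of that library stays open. These SEs are those of the list mean, not of the median. No biological explanation was tested, as the labels hold 1 group.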

How the results depend on the processing

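Alternatives that use the column-name series were chosen after seeing the data, as was every setting of the series comparison. Leaving out 1 library leaves 5, where the smallest exact sign-flip p is 0.0625, so those settings were read as values without a test. Of 1095 alternative values, 15 reversed. Where all 6 libraries lie on 1 side, leaving out 1 library or taking 1 series cannot turn the sign, so those settings do not test it. This holds for DMAP1 relative to its complex, whose sign could turn only with CPM (-1.89) or the mean of the complex (-1.81), and did not. List variability stayed at 16 to 21 lists.

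The cause of the following changes was not tested unless stated. Gad1 over VGlut reversed to -1.44 with VGAT as the marker. CPM without length reversed apoptosis (-0.17) and ecdysone response genes (0.14), and the mean of the list reversed temporal factors (-0.073). With no filter on low counts, the reference median fell because more silent genes entered it, and intermediate progenitor (1.01), optic lobe patterning (0.99), heat shock (0.81), ecdysone response (0.50), hemocyte (0.028), muscle (0.75), ring gland (0.63) and wing and leg disc genes (0.40) reversed, with 24 lists past the threshold above and 6 below, against 17 and 15. Monoaminergic genes, which had not passed, reversed to 0.337 with CPM, 0.241 with the mean of the list and 1.51 with no filter. Genes varying among the libraries rose from 0 to 4 with no filter on low counts and to 49 as DESeq2 dispersion outliers.

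The series comparison gave 158 calls, 959 by DESeq2's Wald test, 90 with the filter in all 6 libraries (89 shared), and 69 to 457 without 1 library, where fewer libraries enter the fit. With the last digit of the column names as a replicate block it gave 278 calls, 107 higher and 171 lower against 89 and 69, and 138 of the 158 were shared. Libraries of the same number correlated in their deviations at 0.32, -0.19 and -0.26, so the numbers do not pair the libraries, and not every library correlated best with its own number. Under that block the adjusted p of DMAP1 was 0.0507. The alternatives planned for the DMAP1 correlation were not run because no correlation was given. At 31518485 to 37236953 counts per library, 3 counts equal 0.081 to 0.095 CPM, and differences below that were not detectable. Whether a larger difference was detectable depended on the spread between libraries.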

Other observations

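The genes, windows and tests named here were chosen after the results were seen, and no explanation was tested for them. Dcr-2, the Dicer of the small interfering RNA pathway, stood at 4707 ± 733 CPM (SD, n = 6), against 85.7 ± 7.99 for Dcr-1, 355 ± 22.9 for its pathway partner AGO2 and 47.9 ± 6.05 for r2d2. Its level did not pass between the column-name series (log2 fold change 0.19, SE 0.19, adjusted p = 0.56).

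Genes called between the series were counted by chromosome, without a test. On chromosome 2L 48 of 1841 tested genes (2.61%) were called, against 8 of 1697 (0.47%) on chromosome X, 37 of 2061 on 2R, 31 of 2018 on 3L, 26 of 2476 on 3R and 2 of 98 (2.04%) on chromosome 4. The window from 21500001 to 22000000 on 2L held 5 called genes of 27 tested, among them CG31600 and CG11629, and the window from 11500001 to 12000000 on 3R held 5 of 63, among them Hsp70Aa, Hsp70Ab and CG18765.

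Of the temporal identity genes of neural progenitors, Imp stood at 808 ± 413 CPM (SD, n = 6) and Syp, which acts opposite to it, at 1828 ± 178. Neither passed the test for genes varying among the libraries (adjusted p = 0.926 and 0.985 in edgeR), while DESeq2 called Imp a dispersion outlier at 16.8 times the trend.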
